A study of Mus musculus with 14 samples.

How the data were processed

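Gene expression was measured in bulk spinal cord tissue of 14 mice, with 1 library per sample, in 4 groups taken from the sample labels: control uninjured (3), control SCI (4), AstroCSF1KO uninjured (3) and AstroCSF1KO SCI (4), the injured ones at 7 days. Per the labels' protocols, poly(A) RNA was sequenced in paired ends of about 150 bp without keeping the strand. Per the submitters' processing notes, reads were handled with CASAVA 1.8 and HISAT2 on mm39; the program that assigned reads to genes and its annotation are not given in the sources used here. The deposited table holds FPKM values for 56748 genes with their names, lengths and mm39 positions, and names and positions are used as that table gives them. Because strand was not kept, a gene cannot be told from an antisense partner, and reads of near-identical copies, such as the haemoglobin genes Hba-a1 and Hbb-bs and their paralogs, could be divided among them in ways the table does not show.

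From each library's values, reads were recovered as FPKM times gene length over the smallest such product. All values above 0 were whole multiples of it within 0.01 (100% in each library), and on simulated values the recovery was exact. The library totals behind the FPKM equal median-of-ratios size factors of the recovered reads up to a constant (ratio 1 in every library), so the deposited FPKM already hold a normalization between libraries. Recovered reads came to 13263610 to 21969581 per library. They were used for depth, for the floor of 3 reads per library that a value of 0 allows, and for the voom alternative. Reads carry no molecular identifiers, so floors cover counting error only.

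Genes with an FPKM of at least 1 in at least 3 of the 14 libraries were kept, 15155 in all, of which 13098 are protein coding. Values were analysed as log2(FPKM + 1), and every log2 change is on that scale. Limma 3.58.1 in R 4.3.3 fitted a linear model per gene with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes kept; a gene is called at an adjusted p under 0.05. Each comparison between a pair of groups used only their libraries, and the interaction, the difference between the injury responses of the genotypes, used all 14. For Csf1 and 7 other genes of the CSF1, interferon, astrocyte and microglia systems, and for list scores, exact two-sided permutation tests were run within uninjured and within injured cords.

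A total of 41 gene lists of cell types and pathways were fixed, with 707 genes, of which 705 are in the table and 567 were kept; 5 genes are in more than 1 list. The 38 lists with at least 5 kept genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and also with camera's estimated correlation and with fry. A list's score in a library is the mean log2(FPKM + 1) of its members. Many markers are expressed by more than 1 cell type of the cord. Genes named in the text are a fixed set of 8; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, predicted genes left out; and for each list described up to 4 called members with the smallest p or, if none is called, up to 2 with the highest mean FPKM. Where the text names others it says so. The groups, the comparisons with their limma, camera and fry tests, the permutation test of Csf1, the lists, this rule and the alternatives, except those said to be added later, were chosen before the data were examined. The permutation tests of list scores and of their relations, the overlap of the genes called in both genotypes, the shares of genes and libraries without overlap, the thinning and spread of replicates, and the regrouping of libraries were not among them.

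For injury-induced genes, the 4 control SCI libraries were split into pairs in 6 ways; 1 pair against the uninjured controls picked genes called higher, and the other pair against the labelled-knockout injured libraries gave the direction.

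The labels number the replicates but do not say that numbers pair samples across groups. Whether they do was checked by correlating, across genes, each library's deviation from its group mean with that of the same number in the other group. In the control injury comparison these correlations were 0.616, 0.832 and 0.733, with the highest for another number at -0.528, 0.708 and 0.812; replicate 1 stands apart in both groups. The check does not settle pairing, since replicate 3 correlated more with another number and the libraries that stand apart weigh on these deviations. The count with replicate as a block is given beside the main one as an alternative only. Control SCI replicate 4 has no uninjured partner, so it does not bear on the change in that fit. The median change over all genes was -0.0146 there, as in the fit without that library. In the other comparisons at least 1 correlation was below 0.1.

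The alternatives were a pseudocount of 0.1, no filter on low values, a filter of at least 5 FPKM, scaling by the median ratio or to TPM, all 14 libraries in 1 fit (for the interaction, no intensity trend), replicate number as a block, and leaving out each library in turn. Added after the data were seen were fits without the 3 control libraries in which under 5% of detected genes have exactly 1 read, fits of the 7 libraries that are neither among these nor above 2% of reads on rRNA genes, limma voom on recovered reads, and the left-out libraries for the interaction. In the fit of 7 libraries injured labelled knockout has 1 library, which is assumed to vary like the other groups.

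The limma and camera steps were run on simulated data with the real means and spread of 15155 genes, and the values given here are limma's. Of these genes 100 were changed by a log2 of 1 and 100 by 2, all drawn from genes above the median mean. Noise was independent between genes. The simulation therefore covers neither genes of lower mean, nor libraries that deviate together over many genes, nor the correlation that camera presets. Of those changed by 1 and by 2, 5 and 45% were recovered for injury in controls, 94 and 100% for injury with labelled knockout, 2 and 47% for labelled knockout without injury, 40 and 74% after injury, and 18 and 57% for the interaction. False calls were 3 of 53, 13 of 207, 1 of 50, 7 of 121 and 8 of 83. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No sample was left out of the main comparisons.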

Results

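RNA from 14 mouse spinal cord samples was measured by sequencing of poly(A)-selected RNA, with 1 library for each sample. The samples fall into 4 groups: control uninjured (n = 3), control with spinal cord injury (SCI, n = 4), AstroCSF1KO uninjured (n = 3) and AstroCSF1KO with SCI (n = 4). Injured cords were taken 7 days after injury around the lesion, and uninjured cords, by the labels, from the matching level. AstroCSF1KO names an astrocyte knockout of Csf1, the colony-stimulating factor whose receptor, encoded by Csf1r, maintains microglia. Because the tissue holds every cell type of the cord, a level below is a level in the tissue. Whole reads recovered from the deposited FPKM values came to between 13263610 and 21969581 per library.

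In 3 control libraries the reads were spread over genes unlike in the other 11: control uninjured replicate 1, control SCI replicate 1 and control SCI replicate 4. Genes with exactly 1 read made up 1.45 to 2.06% of the genes detected in these 3 libraries and 8.44 to 11.6% in the other 11. Reads on mitochondrially encoded genes were 6.73 to 13.9% against 3.38 to 5.78%, and the genes detected numbered 19474 to 22054 against 24791 to 26333. The nuclear RNA Malat1 stood at 348 to 465 FPKM against 27.7 to 225, and the ribosomal protein gene Rplp1 at 61.2 to 230 FPKM against 289 to 944. A further 4 libraries, all labelled knockout (uninjured replicate 3 and SCI replicates 2, 3 and 4), held 2.89 to 3.99% of reads on rRNA genes, against 0.290 to 0.764% in the other 10. These features and the 2 genes were singled out after their values were seen. Comparisons below that changed without the 3 control libraries are given with their values without them.

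**Figure D1:**
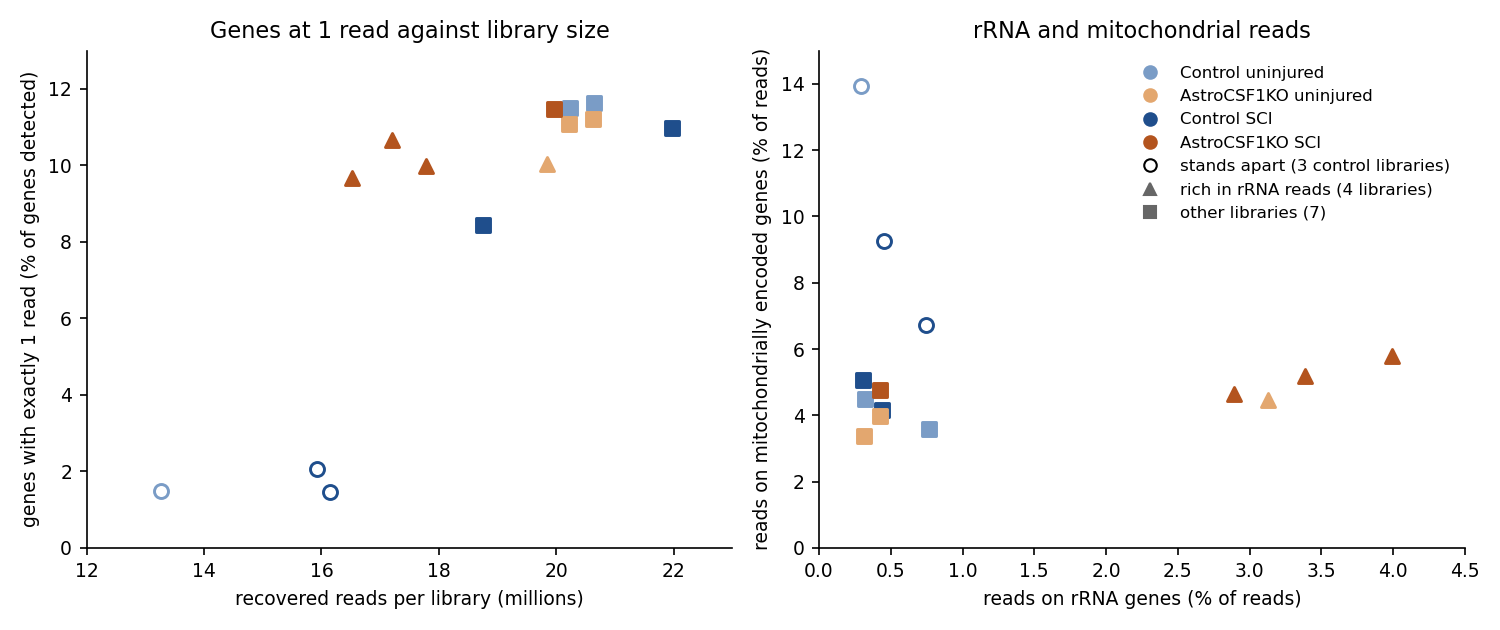
Each point is a library; the left panel plots the percent of detected genes with exactly 1 read against recovered reads, and the right panel the percent of reads on mitochondrially encoded genes against the percent on rRNA genes. The 3 open circles, all control libraries, lie at 1.45 to 2.06% of genes at 1 read, and the 4 triangles, all labelled knockout, at 2.89 to 3.99% rRNA reads.

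Csf1 (ENSMUSG00000014599, chromosome 3, 107648364 to 107667785 of mm39) was measured in every library, as a check of the labels. In uninjured cords it stood at 4.24, 11.9 and 12.2 FPKM in the controls and at 8.23, 10.3 and 11 FPKM in the libraries labelled knockout. In injured cords it stood at 7.95, 17.6, 18.3 and 10.4 FPKM in the controls and at 19.9, 16.4, 18.6 and 19.2 FPKM in those labelled knockout. These values rest on 270 to 2208 reads per library. The group means were 9.46 ± 4.52 FPKM (SD, n = 3) and 9.87 ± 1.45 FPKM (SD, n = 3) without injury, and 13.6 ± 5.18 FPKM (SD, n = 4) and 18.5 ± 1.5 FPKM (SD, n = 4) after it. By these means Csf1 was not lower in the labelled-knockout group in either state. In injured cords the log2 difference, labelled knockout minus control, was 0.49 ± 0.26 (SE, limma adjusted p = 0.477), with an exact two-sided permutation p = 0.143, where 0.0286 is the smallest the design allows. In uninjured cords it was 0.16 ± 0.39 (SE, adjusted p = 0.810) with an exact permutation p = 1, and this design cannot go below 0.1. Without the 3 control libraries that stand apart the differences were 0.04 in injured cords and -0.28 in uninjured cords. Their exact permutation p = 0.733 and 0.2, where 0.0667 and 0.1 are the smallest possible. The uninjured means were then 9.87 FPKM with labelled knockout and 12.1 FPKM in controls, and each uninjured labelled-knockout library lay below both remaining controls. FPKM covers the whole gene and all cells, and the labels do not say which exons were deleted, so neither loss in astrocytes nor its absence can be read from these values. The libraries are called labelled knockout throughout, and every direction between genotypes rests on those labels.

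**Figure D2:**
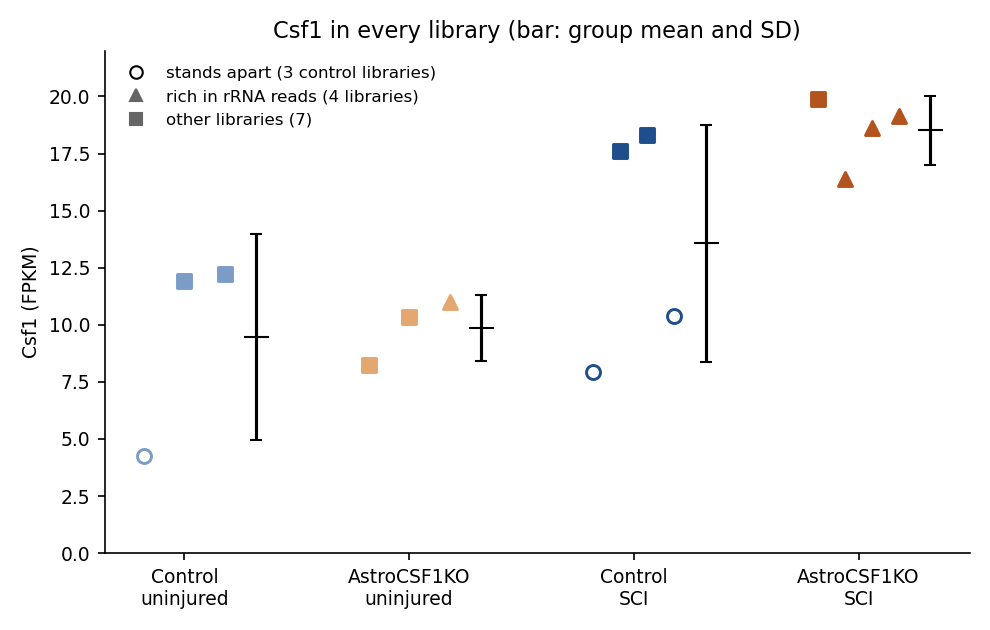
Csf1 in FPKM in each of the 14 libraries, by group, with the group mean and SD as a bar; open circles are the 3 control libraries that stand apart and triangles the 4 rich in rRNA reads. The labelled-knockout means of 9.87 and 18.5 FPKM lie above the control means of 9.46 and 13.6 FPKM. Without the open circles the control means are 12.1 FPKM uninjured, above that of labelled knockout, and 18 FPKM injured.

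Ifnb1, the gene of interferon beta (ENSMUSG00000048806, chromosome 4, 88440262 to 88441011), had 0 reads in all 14 libraries, which allows up to 3 reads in each; the floor covers counting error only. The type I interferon-stimulated list is therefore used in its place, though it does not show which interferon acted. The list of interferon gamma-induced genes moved the same way. Its medians on injury were 0.89 in control and 0.71 in labelled-knockout cords, with 4 of 4 injured libraries above every uninjured one in each. Between injured genotypes its median was -0.16, with 3 of 4 labelled-knockout libraries, those rich in rRNA reads, below every control. Camera did not call it there, and an exact permutation of its scores gave p = 0.114. Without injury 2 of 3 labelled-knockout libraries also scored below every control.

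Control cords were compared by injury, 4 injured against 3 uninjured. The Hox genes described below leave open that the level of the cord sampled differed between injured and uninjured cords. Such a difference would coincide with injury in both genotypes. Changes on injury, the falls of neuron genes among them, are therefore differences between these groups. Large rises among called genes included those of activated microglia and macrophages: Lyz2, which encodes lysozyme, went from 9.52 to 738 FPKM (log2 change 6.11 ± 0.26 SE, adjusted p = 2.75e-04) and Gpnmb from 0.311 to 87.4 FPKM (6.07 ± 0.18 SE, adjusted p = 3.73e-05). The lysosomal gene Cd68 rose by 4.79 ± 0.39 and Clec7a, a pattern receptor, by 3.93 ± 0.39 on the log2 scale (SE). Sprr1a and Atf3, which neurons switch on after axon injury, rose by 5.04 ± 0.34 and 3.05 ± 0.19, and the collagen gene Col3a1 by 4.35 ± 0.64. Of 15155 genes tested, 158 were called, 156 higher and 2 lower, and in all 158 the injured and uninjured libraries did not overlap. Called genes are picked by that same difference; over all genes tested the groups did not overlap in 12.6%, against 5.71% by chance.

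In these cords the damage-associated microglia list rose, with 23 of its 24 measured members higher, 15 called among all genes and 18 called when adjusted over the list alone (median log2 change 2.49, camera adjusted p = 9.62e-37). The pan-macrophage list rose in all 16 members (9 called, 16 adjusted over the list alone; median 2.64, adjusted p = 2.67e-30), with Mpeg1 from outside it at 3.86 and its members Fcgr3 at 3.12, Ctss at 2.97 and Aif1 at 2.61. The homeostatic microglia list, genes of surveying microglia, also rose (median 1.14, 16 of 17 members higher, 4 called, 10 adjusted over the list alone, adjusted p = 9.57e-14): Fcrls was called at 3.26, while P2ry12 was not (0.75 ± 0.61 SE, adjusted p = 0.946; 0.35 to 1.31 leaving out 1 library). Csf1r (chromosome 18, 61233670 to 61265221) stood at 12 FPKM without and 46.9 FPKM with injury and was not called (1.92 ± 0.40 SE, adjusted p = 0.0927); without the 3 libraries that stand apart it was called, at 1.94. The CSF1 axis list it belongs to was higher (8 of 8 members higher, 0 called among all genes, 5 adjusted over the list alone, median 1.30, adjusted p = 5.18e-07), a call not held at adjusted p = 0.182 with an estimated correlation.

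Reactive astrocyte genes rose in control cords, with all 25 members higher, 7 called and 17 called when adjusted over the list alone (median 1.55, adjusted p = 2.28e-25). Serpina3n, a protease inhibitor of reactive astrocytes, rose by 3.32 ± 0.29, Timp1 by 3.63 ± 0.55 and Vim by 2.73 ± 0.28 (SE). Gfap, their filament protein, stood at 421 and 1408 FPKM and was not called (1.84 ± 0.45 SE, adjusted p = 0.150), and was called without the 3 libraries that stand apart, at 1.72. Type I interferon-stimulated genes rose, with 35 of 36 members higher, 4 called and 24 called when adjusted over the list alone (median 1.08, adjusted p = 1.91e-24); the 4 were Ifi207 at 2.12, Ifi204 at 1.85, Cxcl10 at 1.84 and Slfn2 at 1.64. Genes of fibroblasts and scar matrix rose in all 24 members (6 called, 22 adjusted over the list alone; median 2.04, adjusted p = 4.79e-29), among them Bgn at 2.84 and Lum at 2.49. Complement genes rose in 12 of 12 members (3 called, 9 adjusted over the list alone; median 1.88, adjusted p = 5.89e-15), with C3ar1 at 3.52 and Itgb2 at 2.87. Chemokines rose in 11 of 13 (3 called, 7 adjusted over the list alone; median 1.27, adjusted p = 7.56e-10), with Ccl12 at 3.09.

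Lower in injured control cords were the neuron and synapse list, in 24 of 24 members (median -0.76, 0 called, 3 adjusted over the list alone, adjusted p = 2.75e-09), and cholesterol synthesis, in 19 of 19 (median -0.70, 0 called, 1 adjusted over the list alone, adjusted p = 1.26e-09). Nefl, a neurofilament gene, was not called at -0.78; it was called without the 3 libraries that stand apart, at -0.78. The 2 genes called lower were Hsd11b1, which activates glucocorticoids (8.42 to 2.91 FPKM, log2 change -1.28 ± 0.21 SE, adjusted p = 0.0401), and Hoxc12 (2.12 FPKM to 0 reads in all 4 injured libraries, where 3 reads would be 0.125 to 0.242 FPKM, adjusted p = 0.0244). Haemoglobin and other erythroid genes were higher, with 6 of 6 members up (0 called, 5 adjusted over the list alone; median 4.29, adjusted p = 5.18e-07), a call not held at adjusted p = 0.112 with an estimated correlation. For each list named here except those of falling genes all 4 injured libraries scored above every uninjured library, and for the 2 falling lists all 4 scored below. Camera called 22 of 38 lists, of which 17 held with an estimated correlation and 19 were also called by fry. Without the 3 libraries that stand apart it called 27, of which 0 held with an estimated correlation and 24 were also called by fry.

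The number of genes called in control cords moved with the libraries used. Without the 3 that stand apart 3624 genes were called, 1850 higher and 1774 lower, and the 28 called genes named above were all still called. Of those 28, 14 were still called with no filter on low values and 17 by voom. With the replicate number as a block 1030 genes were called, in a fit where control SCI replicate 4 has no partner and does not bear on the change. In the fit without those 3, Xist marks both uninjured controls that remain as female and Ddx3y both injured ones as male, so sex and injury coincide there. Leaving out a single library gave 63, 15 and 17 genes (control uninjured replicates 1, 2 and 3) and 98, 60, 60 and 125 (control SCI replicates 1, 2, 3 and 4), with 10 to 22 of those 28 still called.

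In cords labelled knockout, 4 injured libraries were compared with 3 uninjured ones. The largest rises were again Gpnmb (0.314 to 127 FPKM, log2 change 6.46 ± 0.35 SE, adjusted p = 1.17e-05), Lyz2 (6.27 ± 0.27 SE) and Sprr1a (6.03 ± 0.13 SE), followed by Cd68 (4.91 ± 0.19 SE) and Clec7a (4.23 ± 0.08 SE). Csf1r rose from 14 to 59.9 FPKM (2.02 ± 0.07 SE, adjusted p = 2.22e-06) and Gfap from 493 to 1898 FPKM (1.95 ± 0.13 SE, adjusted p = 2.58e-05). Csf1 itself rose by 0.85 ± 0.10 (SE, adjusted p = 4.15e-04), and was higher in 4 of 4 injured libraries than in any uninjured one. Of 15155 genes 6943 were called, 2991 higher and 3952 lower. In a fit of all 14 libraries together 1141 were called, with the opposite balance of 836 higher and 305 lower, and with median-ratio scaling 3337 were higher and 3432 lower. The groups did not overlap in 6714 of the 6943, which are picked by that same difference, and in 50.7% of all genes tested, against 5.71% by chance.

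Damage-associated microglia genes rose in 24 of 24 members (23 called, 23 adjusted over the list alone; median 2.59, adjusted p = 2.98e-18), with Cst7 at 3.98 and Trem2, a lipid receptor of microglia, at 3.32. Homeostatic microglia genes rose as well (median 1.42, 16 of 17 higher, 15 called, 16 adjusted over the list alone, adjusted p = 6.90e-12): Fcrls by 3.79, Cx3cr1 by 2.23, Tmem119 by 1.42 and P2ry12 by 1.03. These 2 lists held with an estimated correlation, at adjusted p = 0.0465 and 0.0224. The pan-macrophage list rose in all 16 members, each called both ways of adjusting, over all genes and adjusted over the list alone (median 2.91, camera adjusted p = 1.05e-14, adjusted p = 0.14 with an estimated correlation), with C1qb at 3.53, Ctss at 3.11 and Aif1 at 2.26. The CSF1 axis rose in 7 of 8 members (7 called, 7 adjusted over the list alone; median 1.75, camera adjusted p = 1.41e-06, adjusted p = 0.0951 with an estimated correlation).

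Reactive astrocyte genes rose in 24 of 25 members (23 called, 23 adjusted over the list alone; median 1.74, camera adjusted p = 1.54e-14, adjusted p = 0.0951 with an estimated correlation), with Serpina3n at 3.76, C4b at 2.31 and Hspb1 at 2.26. Of 36 interferon-stimulated genes 35 rose and 1 fell, over all genes and adjusted over the list alone (median 0.86, camera adjusted p = 3.86e-13, adjusted p = 0.14 with an estimated correlation); among them were Bst2 at 1.99, Ifitm3 at 1.65 and Oasl2 at 0.96. The list of type I interferon sensing rose (median 0.56, 15 of 18 called higher and 1 lower, 16 and 1 adjusted over the list alone, camera adjusted p = 1.03e-06, adjusted p = 0.0941 with an estimated correlation), with Tlr7, an RNA sensor, at 2.27 and Irf8 at 2.0. Scar matrix genes rose in 24 of 24 members, each called over all genes and adjusted over the list alone (median 1.77, camera adjusted p = 4.85e-11, adjusted p = 0.257 with an estimated correlation), with Bgn at 2.39, Thbs2 at 1.79 and Sparc at 0.71. Complement genes rose in 12 of 12 (11 called, 11 adjusted over the list alone; median 2.27, camera adjusted p = 3.09e-07, adjusted p = 0.0782 with an estimated correlation). Of 6 erythroid genes 5 rose and 1 fell, over all genes and adjusted over the list alone (median 2.95, camera adjusted p = 0.00408, adjusted p = 0.388 with an estimated correlation). Atf3 rose by 3.57.

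Neuron and synapse genes fell in labelled-knockout cords, with 24 of 24 lower, 23 called and 23 called when adjusted over the list alone (median -0.71, camera adjusted p = 5.49e-10, adjusted p = 0.12 with an estimated correlation). Kcnc1, a potassium channel of fast-firing neurons, fell by 1.13, Slc32a1, the transporter that loads GABA and glycine into vesicles, by 1.08, and the neuronal transcription factor Scrt1 by 1.35. Cholesterol synthesis genes fell in 19 of 19, each called over all genes and adjusted over the list alone (median -0.77, camera adjusted p = 6.01e-09, adjusted p = 0.198 with an estimated correlation), with Insig1 at -1.17. The genes around Csf1 on its chromosome moved both ways, with 4 of 21 called higher and 11 lower, the same numbers adjusted over the list alone (median -0.38, camera adjusted p = 0.0339, adjusted p = 0.14 with an estimated correlation). In all of these lists the 4 injured libraries scored on the list's side of every uninjured library. Camera called 23 of 38 lists, of which 2 held with an estimated correlation and 23 were also called by fry. Of the 7 injured and uninjured libraries here, 4 are rich in rRNA reads, 3 of them injured. In the 7 libraries that neither stand apart nor are rich in rRNA 3795 genes were called, 1887 higher and 1908 lower.

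The largest falls among called genes with labelled knockout were Hox genes, transcription factors that mark position along the body axis. Hoxd10 fell by 3.14 ± 0.26 (SE, adjusted p = 6.24e-05), Hoxa10 by 1.61 ± 0.31 and Hoxc10 by 1.57 ± 0.40 (SE). Hoxc11 and Hoxc12 went from 3.22 and 2.79 FPKM to 0 reads in all 4 injured libraries, where 3 reads would be at most 0.123 and 0.242 FPKM. A look at all Hox genes kept, chosen after these values were seen, gave a median change of -1.61 in both genotypes over the 7 genes of groups 10 to 12. With genes at 0 reads in a group set to 3 reads per library the medians were -1.45 in control and -1.61 in labelled-knockout cords. All 7 were called lower with labelled knockout, 1 in control cords, and 7 in control cords without the 3 libraries that stand apart. In the 15 genes of groups 4 to 8 the medians were -0.30 in control cords, where 0 were called, and -0.33 with labelled knockout, where 5 were called lower. Hoxc10 was no longer called without AstroCSF1KO uninjured replicate 2 or 3 (-1.37 and -1.42). In the fit of all 14 libraries 28 of the 37 called genes named for injury with labelled knockout were still called. Those that lost their call were P2ry12, Tmem119, Hspb1, Bst2, Kcnc1, Slc32a1, Scrt1, Hoxa10 and Hoxc10.

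**Figure D3:**
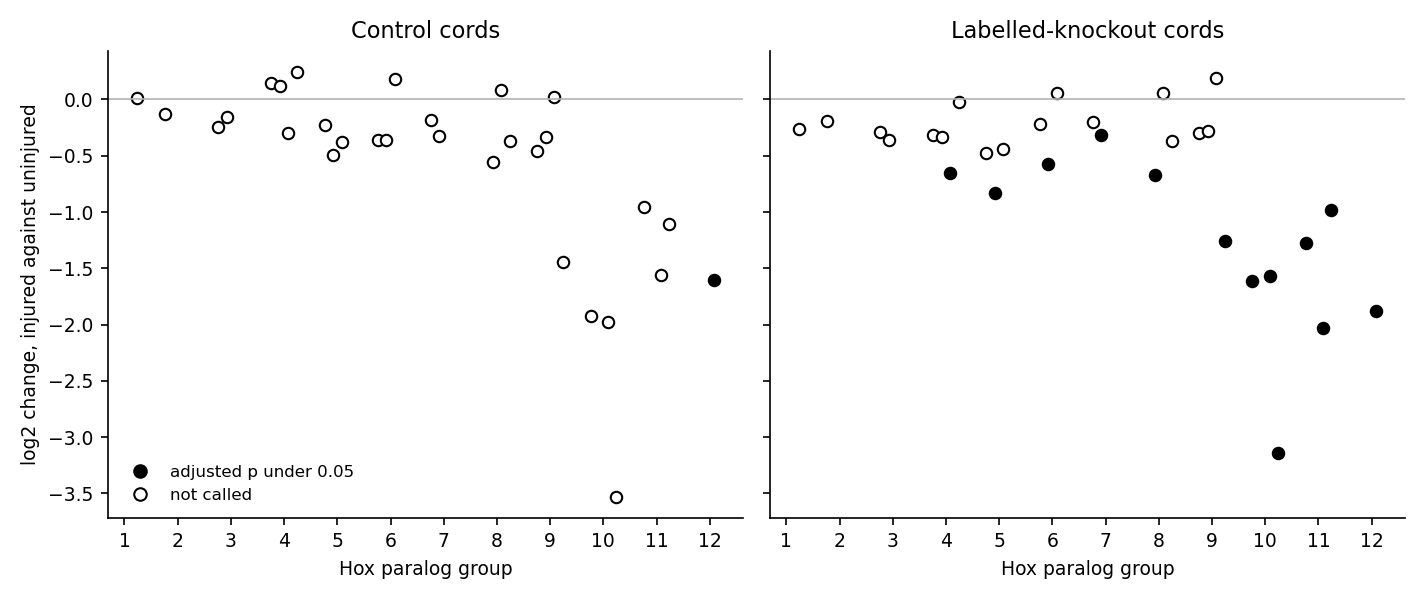
Log2 change of each Hox gene kept, injured against uninjured cords, by paralog group from 1 to 12, in control cords (left) and labelled-knockout cords (right); filled points have an adjusted p under 0.05. The 7 genes of groups 10 to 12 have a median of -1.61 in both, and 1 of them is called in control cords and 7 in labelled-knockout cords.

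Both genotypes could be compared in the genes they called, since they share no library. Of the 156 genes that rose in control cords 155 also rose with labelled knockout, against 30.8 if the lists were independent, and both genes that fell also fell. The log2 changes of the 15155 genes correlated across genes at Pearson r = 0.874, though genes are not independent replicates. Without the 3 libraries that stand apart 1511 of 1850 genes that rose and 1519 of 1774 that fell in control cords did so with labelled knockout, against 365 and 463 for independent lists, and r was 0.836.

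**Figure D4:**
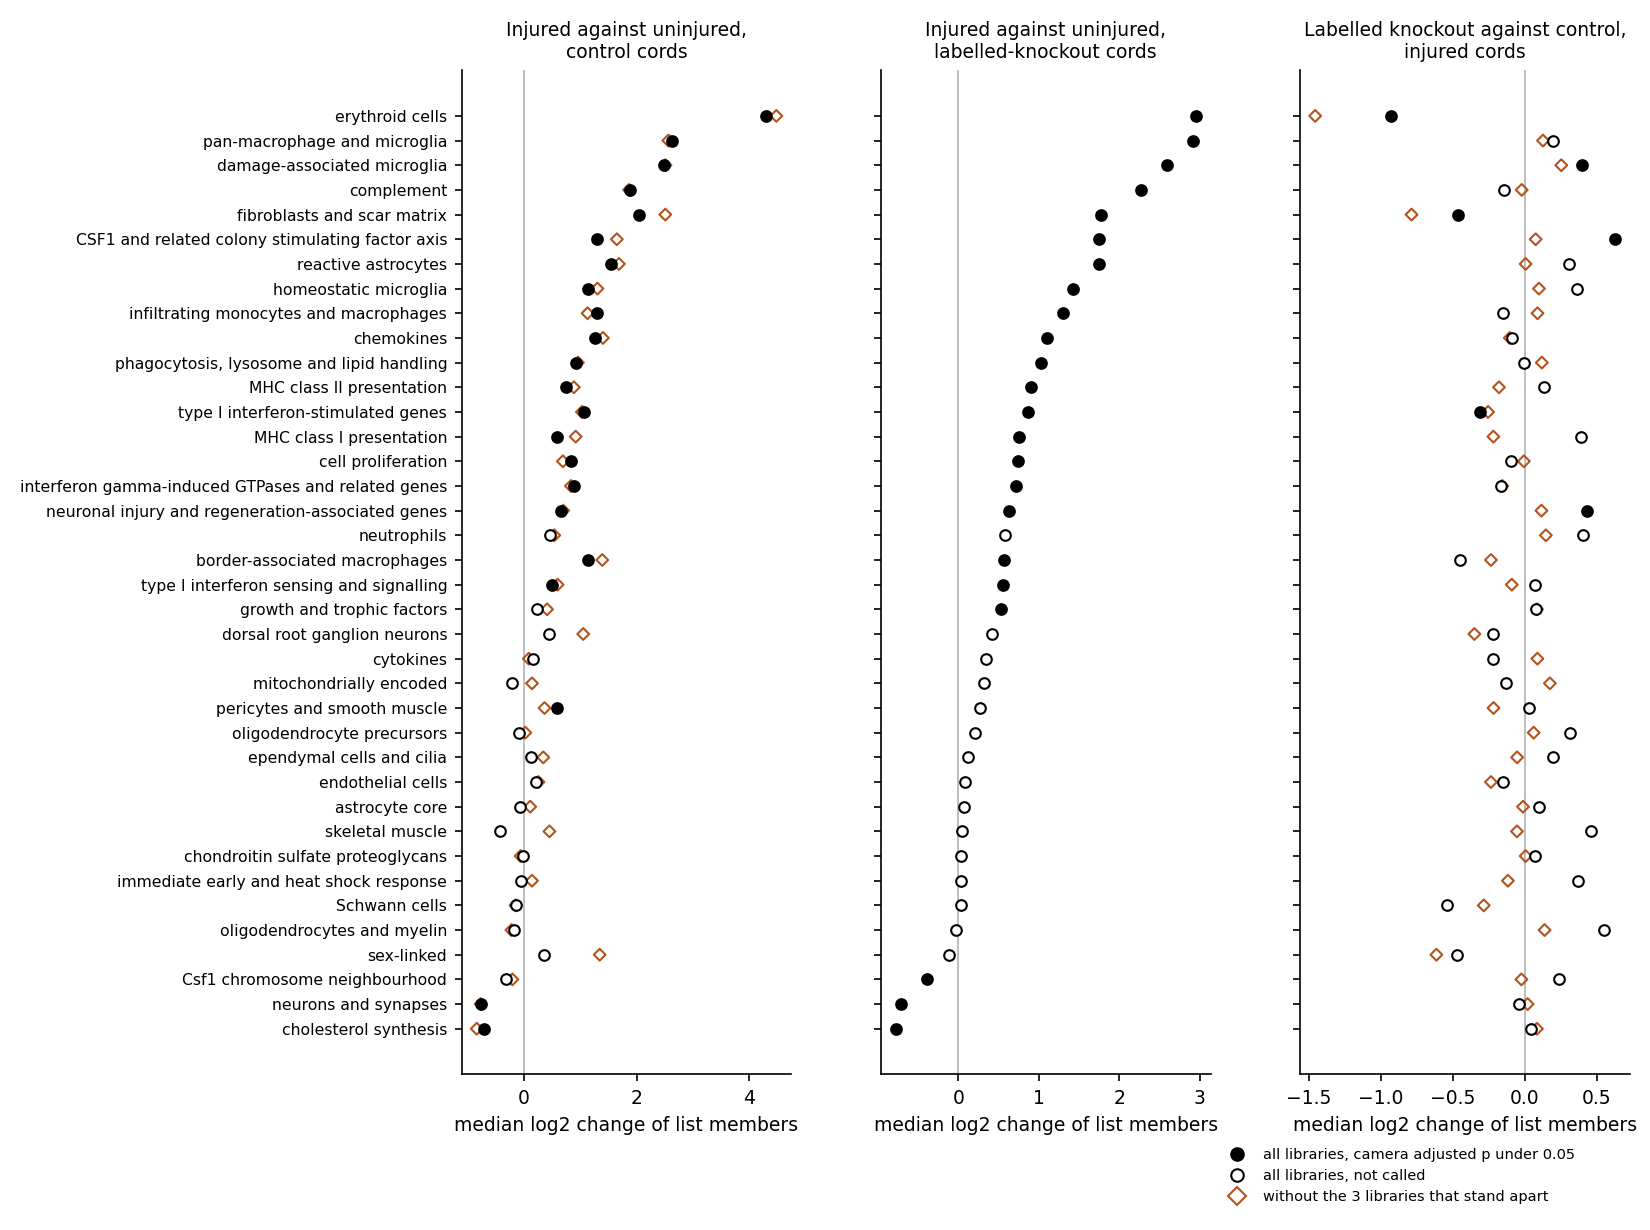
Median log2 change of the members of each of the 38 lists tested, for injury in control cords, injury in labelled-knockout cords and labelled knockout against control in injured cords; filled circles have a camera adjusted p under 0.05 and diamonds leave out the 3 libraries that stand apart. The damage-associated microglia list lies at 2.49 and 2.59 on injury and at 0.40 between injured genotypes, and the neuron list at -0.76 and -0.71 on injury.

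Without injury, 3 labelled-knockout libraries were set against 3 controls, which asks what the deletion does in the resting cord. P2ry12, a purine receptor of surveying microglia, stood at 7.64 FPKM with labelled knockout and 16.9 FPKM in controls (log2 difference -0.81 ± 0.48 SE, adjusted p = 0.603), and at -0.24 without control uninjured replicate 1, which stands apart. Tmem119 and Aif1, also of microglia, went the other way (0.45 and 0.35, neither called), and stood at -0.03 and 0.21 without that library. Il34, which encodes the other ligand of the CSF1 receptor, was not called (0.81, and 0.20 without it). Csf1r differed by 0.31 ± 0.35 (SE, adjusted p = 0.641), and by -0.09 without that library. Schwann cell genes were lower in 8 of 10 members (median -0.66, camera adjusted p = 0.0647), with Pmp22, of peripheral myelin, at -1.08 ± 0.47 (SE). Mitochondrially encoded genes were lower in 12 of 13 (median -0.45, camera adjusted p = 0.0647). Neither list was called here, but of 11 alternatives 5 called the Schwann cell list and 3 the mitochondrially encoded list. Both medians moved with single libraries: the mitochondrially encoded one was -0.04 without control uninjured replicate 1 and -1.08 without replicate 3, and the Schwann cell one -0.19 without labelled-knockout uninjured replicate 3. The scar matrix list was not called either (median -0.11, adjusted p = 0.202), and was called lower without control uninjured replicate 1, at -0.28. That call did not hold: without that library the lowest adjusted p of any list was 0.91 with an estimated correlation, and fry called 0. Limma called 0 of 15155 genes, with 331 at an unadjusted p under 0.05, and voom also 0. Leaving out 1 library kept limma at 0 called, with 76 to 1973 genes at an unadjusted p under 0.05. The highest was without control uninjured replicate 1. Over all genes tested the groups did not overlap in 23.3%, against 10% by chance, though genes are not independent. The lack of calls does not show that the genotypes are alike. Of 38 lists 0 were called.

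In the 7 libraries that neither stand apart nor are rich in rRNA, 2 of each genotype were uninjured and 5 genes were called. These were Xist at -4.22, Ddx3y at 3.73, Eif2s3y at 2.73, Gm49980 at -1.88 and Gm29650 at 1.82, named after their values were seen; the former 3 mark the sex of the animal. The labels give no sex; Xist stood at 13.4 to 49.3 FPKM in 6 libraries and at 0.210 FPKM or less in the other 8, and over all 14 libraries each group holds both kinds. Among these 7, both uninjured controls carry Xist (15.2 and 20.6 FPKM) and both uninjured labelled-knockout libraries Ddx3y (13.3 and 11.2 FPKM). Sex and genotype therefore coincide there.

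After injury, the comparison the series' title is about, 4 labelled-knockout libraries were set against 4 controls. Type I interferon-stimulated genes were lower as a list, with 29 of 36 members down (median -0.31, camera adjusted p = 1.58e-04, adjusted p = 0.754 with an estimated correlation) and 3 of 4 labelled-knockout libraries scoring below every control. Genes of fibroblasts and scar matrix were also lower, in 19 of 24 members (median -0.46, camera adjusted p = 9.71e-04, adjusted p = 0.754 with an estimated correlation). Erythroid genes were lower in 6 of 6 (median -0.93, camera adjusted p = 0.0158, adjusted p = 0.754 with an estimated correlation). For these 2 lists 0 of 4 libraries scored below every control. Damage-associated microglia genes were higher in 21 of 24 members (median 0.40, camera adjusted p = 0.00206, adjusted p = 0.754 with an estimated correlation) and regeneration-associated neuronal genes in 11 of 14 (median 0.43, camera adjusted p = 0.0158, adjusted p = 0.754 with an estimated correlation), with 4 of 4 libraries above every control in both. The CSF1 axis was higher in 8 of 8 members (median 0.63, camera adjusted p = 0.00415, adjusted p = 0.754 with an estimated correlation), with 2 of 4 libraries above every control.

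None of these 6 calls held with an estimated correlation, and fry called 0. Of their members 0 were called among all genes, and when adjusted over the list alone 3 regeneration-associated genes were called and 0 in the other 5 lists. An exact permutation of the list scores gave p = 0.0857 for interferon-stimulated genes (difference -0.20), 0.371 for scar matrix (-0.49) and 0.0286 for damage-associated microglia (0.47), the smallest the design allows. Regeneration-associated genes (0.42), homeostatic microglia (0.35) and growth and trophic factors (0.18) also reached an exact permutation p = 0.0286. Over 38 lists the lowest adjusted p of this test was 0.271. Without the 3 libraries that stand apart the damage-associated score differed by 0.20 (exact permutation p = 0.133, where 0.0667 is the smallest possible) and the regeneration-associated score by 0.18 instead of 0.42. Limma called 0 of 15155 genes, with 497 at an unadjusted p under 0.05, and voom also 0. Leaving out 1 library kept limma at 0 called. The genes at an unadjusted p under 0.05 then ran from 167, without labelled-knockout SCI replicate 3, to 2893 and 2916, without control SCI replicates 2 and 3. The groups did not overlap in 3.15% of all genes tested, against 2.86% by chance.

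Among abundant members of these lists, none of them called, Ctsd and Apoe, of lysosomes and lipid transport, differed by 1.72 ± 0.72 and 1.35 ± 0.67 (SE), labelled knockout minus control, and by 0.33 and 0.02 without the 3 control libraries that stand apart. Ifitm3 and Ifi27, both interferon-stimulated, differed by 0.39 and 0.60 against their list's direction, and by -0.22 and -0.26 without those libraries. Col1a1 differed by -0.52, by -1.31 without them and by -0.03 without control SCI replicate 3. Hba-a1 and Hbb-bs differed by -1.04 and -0.66, with values from -1.90 to -0.23 and from -1.61 to 0.08 leaving out 1 library, and by -1.82 and -1.43 without the 3. Gap43, of growing axons, differed by 0.45 and by 0.10 without the 3. Csf1r, Gfap and P2ry12 differed by 0.41 ± 0.24, 0.48 ± 0.23 and -0.52 ± 0.41 (SE, adjusted p = 0.477, 0.477 and 0.480), and by -0.01, 0.09 and 0.17 without those libraries. Tmem119 and Il34 differed by 1.07 ± 0.65 and 0.69 ± 0.56 (SE, adjusted p = 0.477 and 0.484), and by -0.23 and -0.35 without them.

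The lists moved with single libraries. Without control SCI replicate 3 the scar matrix list stood at -0.17 and the regeneration-associated list at 0.52, both no longer called, and without control SCI replicate 2 the erythroid list stood at -0.30 and was no longer called. Without control SCI replicate 4 the interferon-stimulated list stood at -0.19 and the erythroid list at -1.81, and without control SCI replicate 1 the scar matrix list stood at -0.77, the damage-associated list at 0.25 and the erythroid list at -0.60, all still called. Without the 3 libraries that stand apart 14 lists were called, 5 higher and 9 lower, and in the 7 libraries that neither stand apart nor are rich in rRNA 15, with the opposite balance of 13 higher and 2 lower. Without the 3 the interferon-stimulated and scar matrix lists stood at -0.26 and -0.79, the erythroid list at -1.46, the damage-associated list at 0.25 and the regeneration-associated list at 0.12. These 5 were called, and the CSF1 axis at 0.08 was not. None of these 14 calls held: the lowest adjusted p was 0.699 with an estimated correlation, and fry called 0. The interferon-stimulated list lost its call with genes under 5 FPKM left out (-0.003), and so did it, at -0.06, and the scar matrix list, at -0.08, in the 7 libraries that neither stand apart nor are rich in rRNA, where 1 injured library is labelled knockout. Of 11 alternatives that keep or drop whole sets of libraries or change the values or test, 8 kept the interferon-stimulated list called, with adjusted p from 3.94e-10 to 0.754.

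**Figure D5:**
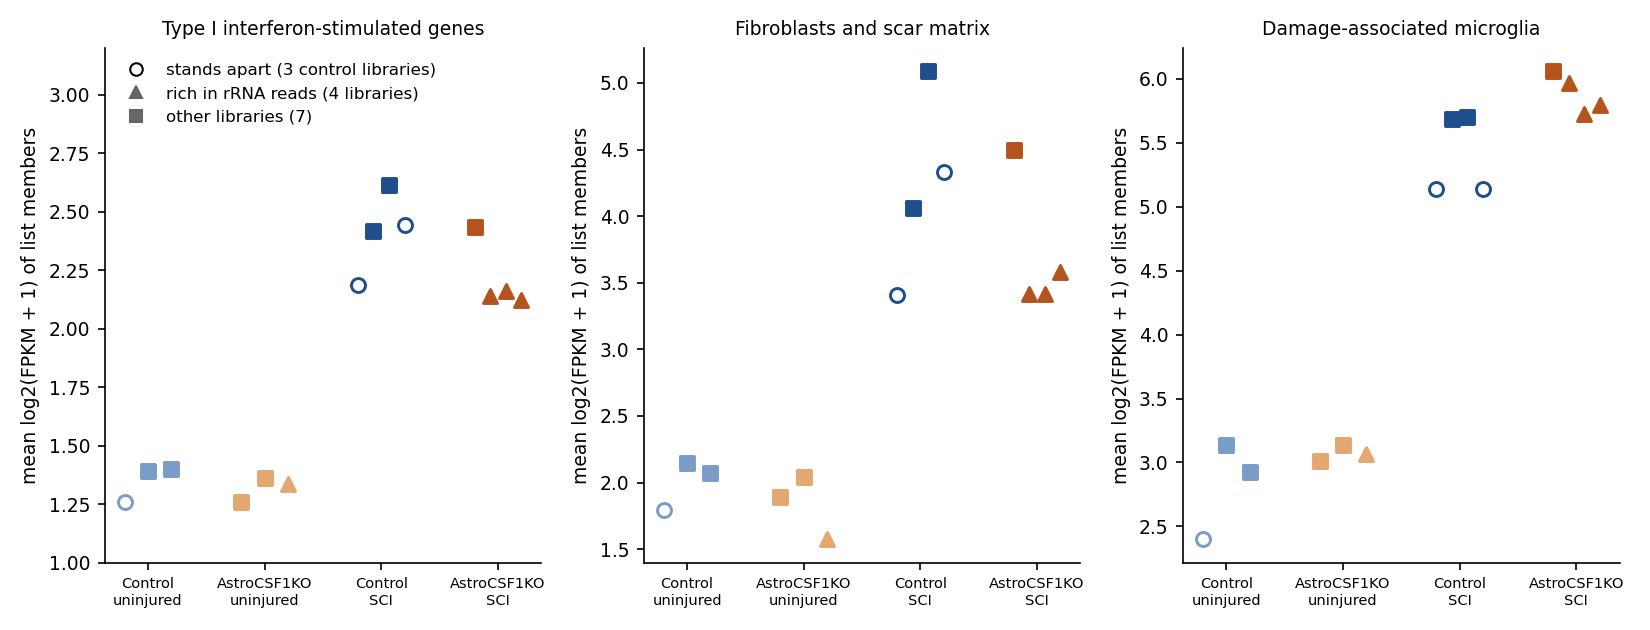
Mean log2(FPKM + 1) of the members of 3 lists in each library, by group; open circles are the 3 control libraries that stand apart and triangles the 4 rich in rRNA reads. In injured cords the interferon-stimulated scores run from 2.19 to 2.61 in controls and are 2.12, 2.14 and 2.16 in the 3 labelled-knockout libraries rich in rRNA and 2.43 in the other.

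Genes raised by injury were then asked about directly, with the injured controls split so that those that picked the genes were not those compared with labelled knockout. Over 6 such splits 1 to 125 genes were picked, and the median share lower with labelled knockout was 5%, between 0 and 66.7%, with a median log2 difference of 0.33. That median rests on few genes: 5 of the splits held 1, 2, 2, 3 and 10, and in the split of 125, picked with control SCI replicates 2 and 3, the share was 28.8%. That split sets labelled knockout against control SCI replicates 1 and 4, both of which stand apart. Without the 3 libraries that stand apart 2 splits remained, with 426 and 716 genes, a median share of 50.02% and a median difference of -0.005. Without control uninjured replicate 1 the share was 24.5%, without replicate 2 or 3 of that group no gene was picked, and it was 0, 0, 10 and 24% without control SCI replicates 1, 2, 3 and 4. It was 0% without labelled-knockout SCI replicate 3 or 4 and 5% without replicate 1 or 2.

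Whether injury acted differently in the 2 genotypes was tested over all 14 libraries. The response of erythroid genes was smaller with labelled knockout (median difference in log2 change -1.38, 0 of 6 members higher, camera adjusted p = 5.75e-06, adjusted p = 0.566 with an estimated correlation). So was that of interferon-stimulated genes (-0.19, 28 of 36 lower, camera adjusted p = 6.33e-05, adjusted p = 0.566 with an estimated correlation) and scar matrix genes (-0.30, 23 of 24 lower, camera adjusted p = 0.00109, adjusted p = 0.761 with an estimated correlation). It was larger for mitochondrially encoded genes (0.41, 12 of 13 higher, camera adjusted p = 0.00109, adjusted p = 0.658 with an estimated correlation), damage-associated microglia (0.17, 22 of 24, camera adjusted p = 0.00389, adjusted p = 0.612 with an estimated correlation) and homeostatic microglia (0.20, 15 of 17, camera adjusted p = 0.0145, adjusted p = 0.566 with an estimated correlation). All 6 calls were thus lost with an estimated correlation, and fry called 0. Without control SCI replicate 2 or 1 the erythroid difference was -0.74 or -0.92, still called. Where leaving out 1 library kept the call, the difference ran from -0.61 to -0.16 for scar matrix and from -0.29 to -0.13 for interferon-stimulated genes. It ran from 0.33 to 0.88 for mitochondrially encoded genes and from 0.10 to 0.38 for damage-associated microglia, the highest without control uninjured replicate 1. Single libraries ended calls too: that of interferon-stimulated genes without control SCI replicate 4 (-0.13), of scar matrix without control uninjured replicate 1 (-0.13) or control SCI replicate 3 (0.02) or 4 (-0.34), and of mitochondrially encoded genes without control uninjured replicate 1 (-0.05) or labelled-knockout uninjured replicate 1 (0.36). The damage-associated call ended without control uninjured replicate 2 (0.08) or control SCI replicate 1 (0.15) or 4 (0.05), and the homeostatic call without control uninjured replicate 1, 2 or 3 (0.30, 0.18 and 0.23), control SCI replicate 1 or 4 (0.12 and 0.16) or labelled-knockout uninjured replicate 1 (0.20). Without the 3 libraries that stand apart 5 lists were called, among them scar matrix (-0.55), erythroid (-1.65) and interferon-stimulated genes (-0.15), and the mitochondrially encoded (0.15), damage-associated (0.20) and homeostatic lists (0.02) were not among them. None of the 5 held: the lowest adjusted p was 0.909 with an estimated correlation, and fry called 0. By Xist and Ddx3y the uninjured controls left are female and the injured ones male, so sex and injury coincide among the controls there. They also do in the 7 libraries given below, where every labelled-knockout library carries Ddx3y. Without the 3 libraries limma called 0 genes, with 2158 at an unadjusted p under 0.05. Csf1 differed by 0.33 ± 0.47 (SE, adjusted p = 1). Limma called 0 of 15155 genes, with 91 at an unadjusted p under 0.05, and voom 0; in the 7 libraries that neither stand apart nor are rich in rRNA it called 4, Xist, Ddx3y, Eif2s3y and Gm49980, named after their values were seen.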

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

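The tests of the 3 libraries that stand apart as the source of the interferon list's difference, of rRNA-rich libraries, of scar tissue and of the Hox genes were chosen only after the results were seen, and so were the depth test and the requirement of a permutation p under 0.05 in the scar tissue test.

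In 3 control libraries few genes have exactly 1 read, and they hold more mitochondrial reads and fewer detected genes than the other 11. Lower depth is argued against: thinned to the smallest library, the other 11 still had at least 9.73% of detected genes at 1 read, against at most 2.06%. For removal of low read numbers in the processing, the prediction was replicates as close as others at 5 to 10 reads. By the median squared difference between replicates, the apart pair of injured controls stood at 12.8 times the Poisson value and the other pair at 1.83 times. This does not decide on removal, since values set to 0 in 1 library of a pair would widen that spread too. The apart pair also spread more at 1000 to 5000 reads (77.6 against 9.22 by the same ratio of squared differences) and differs in Ddx3y (23.6 and 0 FPKM). Few starting molecules amplified into many reads remains a candidate explanation, since it predicts that wider spread. No biological explanation was tested, as the 4 other control libraries of the same groups do not show the pattern.

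In injured cords the interferon-stimulated and scar matrix lists were lower with labelled knockout; of abundant matrix genes, Col1a1 stood at 104 FPKM in controls and 64.9 FPKM with labelled knockout, and Sparc at 572 and 588 FPKM. The 3 libraries that stand apart are argued against as the whole cause, since the interferon-stimulated median was -0.26 without them against -0.31 with them, and the list was still called. That argument is weak, as the call did not hold with an estimated correlation (lowest adjusted p of any list 0.699). The list's score there had an exact permutation p = 0.133, but this test cannot go below 0.0667 without those libraries and so decides nothing. The rRNA-rich libraries cannot be told apart from the genotype: among the 7 libraries that are neither, the median was -0.055, but with 1 labelled-knockout injured library and no rRNA-rich injured control. Less scar tissue in the sampled piece may account for it, as the interferon-stimulated and matrix scores of the 8 injured libraries went together (Pearson r = 0.966, exact permutation p = 0.00198, adjusted 0.00992 over 5 relations; Spearman rho = 0.738, exact permutation p = 0.0458; r = 0.946 without the 2 farthest libraries; too few of each kind of library for an r within kinds), and the difference of -0.20 ± 0.114 in score (SE) became -0.074 ± 0.029 (SE) with the matrix score as covariate, more than 2 SE below 0, which speaks against scar tissue as the whole cause, while the exact permutation p = 0.114 leaves that undecided. An effect of the knockout on both lists is open as well, and these data do not decide between them.

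Hox genes of groups 10 to 12 were lower in injured cords of both genotypes. A like loss of Hox-expressing cells of all groups at the lesion is argued against. Groups 4 to 8, from the same tissue, had medians no lower than -0.33 against -1.61 for groups 10 to 12. Of their 15 genes, 10 were lower in control cords and 13 with labelled knockout. These values do not bear on a loss of cells that carry groups 10 to 12 alone. Sampling of another level of the cord would go against the labels, which put the uninjured tissue at the corresponding segments, but may account for it, as groups 10 to 12 fell by 1.28 more than groups 4 to 8 in the genotype with the smaller gap. An effect of injury on these genes alone stays open, since no value here separates it from a shift in level.

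Groups of 4 values, 102 in all, were examined over library measures, the fixed genes and list scores. Chance gives about 5% per group, but lists that move together are not independent, so no expected number follows. In 7 groups, all of them list scores, a library lay far from its 3 group members. Of these 6 belong to labelled-knockout SCI replicate 1, the injured labelled-knockout library that is not rich in rRNA. It scored 2.43 for interferon-stimulated genes (others 2.12 to 2.16), 3.46 for endothelial cells (3.17 to 3.21), 3.19 for pericytes and smooth muscle (2.59 to 2.66) and 4.5 for scar matrix (3.42 to 3.58). It also scored 4.79 for skeletal muscle (0.405 to 0.871) and 1.69 for cell proliferation (1.48 to 1.51). Labelled-knockout SCI replicate 4 scored 3.42 for dorsal root ganglion neurons (1.76 to 1.78).

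The injury response of 6 lists differed between genotypes by camera, labelled knockout minus control: -0.19 for interferon-stimulated genes, -0.30 for scar matrix, -1.38 for erythroid cells, 0.20 for homeostatic microglia, 0.17 for damage-associated microglia and 0.41 for mitochondrially encoded genes. None held with an estimated correlation, where the lowest adjusted p was 0.566.

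Regrouping the libraries tested each count against other splits of the same samples, and the rule for it, a share of splits under 0.05, was written after the counts were seen. For the genes called on injury with labelled knockout 1 of 35 splits, the real one, gave 6943, and the highest other gave 5. That meets the rule at the smallest share 35 splits allow, and argues against chance. For genes called on injury in controls 2 of 35 splits gave 158 or more, so the splits alone do not exclude chance. The labelled-knockout libraries share no sample with the controls. Of the 156 genes that rose in controls, 155 were called higher there too, against 30.8 for independent lists, and 0 lower. Genes that move together are not independent, so this overlap argues against chance without giving it a level. The highest other split gave 8461; it sets control uninjured replicates 2 and 3 with control SCI replicates 2 and 3 against the 3 libraries that stand apart, a structure of the samples whose cause is open, and without those 3 the injury comparison gave 3624. The number of lists called is high in many splits and so decides nothing on chance: 13 of 35 gave 22 or more on injury in controls (highest other 25), 15 of 35 gave 23 or more with labelled knockout (29), 22 of 35 gave 6 or more between injured genotypes (20) and 36 of 100 drawn splits gave 6 or more for the interaction (16). For damage-associated microglia, interferon-stimulated genes and scar matrix, all 4 injured libraries lay above every uninjured one in each genotype. With 0 genes called between injured genotypes and for the interaction, all 35 splits (highest other 3) and all 100 (0) give as many by construction, which says nothing on chance. Uninjured genotypes make 10 splits, too few for a share under 0.05; all 10 gave 0 or more genes (highest other 1) and all 10 gave 0 or more lists (highest other 2).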

How the results depend on the processing

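The fits without the 3 libraries that stand apart, of the 7 libraries that neither stand apart nor are rich in rRNA, voom and the left-out libraries for the interaction were chosen after seeing the data; the cause was not tested for any change below, beyond the fewer libraries or the other test that a setting uses. Of the values that answer a comparison 249 kept their direction and side of the threshold (counts, within 1.5 times), 45 moved, 2 became called, 1 lost its call and 4 turned; of single genes and lists 2016 kept both, 196 lost a call, 28 gained one and 21 turned.

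Injury in controls gave 158 genes, and 54 with no filter, 94 above 5 FPKM, 1073 with all 14 libraries in 1 fit, 1030 with a replicate block, 3624 without the 3, 4648 in the 7 and 104 by voom; leaving out 1 library gave 15 to 125. Injury with labelled knockout gave 6943, and 1141 with all 14 in 1 fit and 3795 in the 7. By limma the genotypes differed in 0 genes under every setting except 5 without injury and 4 for the interaction in the 7 libraries. Lists called on injury with labelled knockout numbered 23, and 2 with an estimated correlation, while fry called 25 with those 23 among them. Without injury 0 lists became 1 (no filter, block, without the 3), 2 (5 FPKM, all 14, the 7, voom) and 0 to 3 leaving out 1 library. After injury 6 became 14 without the 3, 15 in the 7, 0 with an estimated correlation, 0 with fry and 5 to 14 leaving out 1. For the interaction 6 became 3 with no filter, 10 in the 7, 3 by voom, 0 with an estimated correlation, 0 with fry and 2 to 12 leaving out 1.

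Csf1 on injury in controls became called at 0.54 without the 3 and in the 7 (0.08 to 0.75 leaving out 1); with labelled knockout it was not called at 0.85 in the fit of all 14 (0.74 to 0.93). Between uninjured genotypes it was -0.28 without the 3 and -0.35 in the 7 (-0.28 to 0.39), between injured ones 0.28 to 0.65 and for the interaction 0.10 to 0.77 leaving out 1. The share of injury-induced genes lower with labelled knockout was 50.02% without the 3 and 0 to 24.5% leaving out 1, with no value without control uninjured replicate 2 or 3. Without injury, Csf1r turned to -0.089 without the 3 and in the 7 (-0.089 to 0.50), and Tmem119 to -0.031 without the 3 and -0.094 in the 7 (-0.031 to 0.71 leaving out 1). After injury these turned without the 3 and in the 7: Csf1r (-0.006, -0.041), Ifitm3 (-0.22, -0.032), Ifi27 (-0.26, -0.087) and Il34 (-0.35, -0.028). P2ry12 turned to 0.17 and Tmem119 to -0.23 without the 3, Gfap to -0.072 in the 7, and Hbb-bs ran from -1.61 to 0.075 leaving out 1. In the interaction the interferon-stimulated and scar matrix lists were 0.002 and 0.038 in the 7, and the mitochondrially encoded list ran from -0.049 to 0.88 leaving out 1. Depth limits genes near the floor of 3 reads, Ifnb1 among them.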

Other observations

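The lists here were tested as planned and picked for description after their values were seen. Cell division genes rose on injury in both genotypes, in 20 of 20 members. In control cords the median log2 change was 0.84 (0 called, 11 adjusted over the list alone, camera adjusted p = 1.01e-13, and adjusted p = 0.00685 with an estimated correlation), and with labelled knockout it was 0.74 (18 called, 18 adjusted over the list alone, camera adjusted p = 1.93e-08, adjusted p = 0.14 with an estimated correlation). Genes of phagocytosis, lysosomes and lipid handling, which clear myelin debris, rose in 17 of 20 members in control cords (median 0.93, 3 called, 11 adjusted over the list alone, camera adjusted p = 3.46e-13, adjusted p = 0.00685 with an estimated correlation) and in 19 of 20 with labelled knockout (median 1.02, 16 called, 16 adjusted over the list alone, camera adjusted p = 2.38e-09, adjusted p = 0.14 with an estimated correlation). MHC class I genes, which present antigen, were above 0 in 10 of 13 members in control cords (median 0.58, 0 called, 0 adjusted over the list alone, camera adjusted p = 9.85e-04, adjusted p = 0.385 with an estimated correlation) and in 12 of 13 with labelled knockout (median 0.76, 11 called, 11 adjusted over the list alone, camera adjusted p = 5.82e-06, adjusted p = 0.192 with an estimated correlation). All 4 injured libraries of each genotype scored above every uninjured one for the former 2 lists, and 2 of 4 in controls and 4 of 4 with labelled knockout for MHC class I.

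Some cell types of the cord, as lists, were not called on injury. Core astrocyte genes stood at a median of -0.07 in control cords and 0.07 with labelled knockout (camera adjusted p = 0.921 and 0.521), with 6 members called higher and 5 lower in the latter. Genes of oligodendrocytes and myelin were lower in 18 of 20 members in control cords (median -0.18, adjusted p = 0.131) and in 11 of 20 with labelled knockout (median -0.02, adjusted p = 0.749). Endothelial genes stood at 0.21 and 0.08 (adjusted p = 0.126 and 0.521).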
